A study of Arabidopsis thaliana with 30 samples.

How the data were processed

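Total RNA of leaf 3 of Arabidopsis thaliana Col-0, grown on MS medium at 22 °C with 16 h of light and 8 h of dark, was measured on AGRONOMICS1 tiling arrays, 1 array per sample. The deposited table holds log2 values that the authors made with RMA (background correction, quantile normalization and a summary of probes per locus) on the TAIR9 annotation, per the submitters' processing notes, and its columns belong to these 30 arrays, with 0 columns of other samples. The version of RMA, the probe definitions and any filter are not given in the sources used here. Array medians and lower quartiles differed between the experiments (lower quartiles 2.91 to 3.10 in the time course and 2.31 to 2.38 in the norflurazon experiment), while the upper quartiles overlapped, so the experiments look normalized apart. They were fitted apart, a choice made before the data were examined, since they may be separate hybridisation batches. Raw intensities were not used here. Values ran from 1.91 to 14.42 in the time course and from 1.40 to 14.31 in the norflurazon experiment. Arrays give no counts, and the number of arrays limits the precision.

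The table held 30237 probe sets for 29920 loci, and all were tested. For 208 loci with several probe sets (525 in all) each probe set was kept as its own row. Symbols came from a reference gene table on the TAIR10.1 assembly, used for names only, which held 29398 of the loci and a symbol for 10528 probe sets. No coordinates are given because the array annotation is on another assembly version.

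Groups followed the labels, 6 ages of 3 arrays in the time course and 4 groups of 3 in the norflurazon experiment. Each experiment was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group, contrasts, eBayes with a constant prior). The time course had 12 residual and 4.32 prior degrees of freedom and the norflurazon experiment 8 and 3.77. The contrasts were the 5 intervals of 1 day, day 13 minus day 8, norflurazon minus control at day 9 and at day 10, the interaction of norflurazon with the day, and day 10 minus day 9 in control and in treated leaves. A moderated F test covered all 6 ages. P-values were adjusted by Benjamini-Hochberg over all probe sets within each contrast, and a call is an adjusted p under 0.05. No filter on dim probe sets was applied. The numbers of the repeats do not pair samples: arrays with the same number in different groups correlated, after the group means were removed, at -0.25 to 0.17 in the time course (45 pairs, 2 over 0.1) and at -0.06 to 0.09 in the norflurazon experiment (18 pairs, 0 over 0.1).

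The comparisons, the alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 6 with the largest rise and the 6 with the largest fall among called genes that have a symbol, separate arrays and a mean at or above the median of all probe sets in the higher group, up to 2 called members of each list with the largest change, and 20 genes given whatever their values. Separate arrays means that all 3 arrays of a group lie above the 3 of the other, which chance gives in 10% of cases for 3 against 3. Changes of genes shared by comparisons are given where a comparison is described. The lists held 549 entries, of which 11 were not measured, among them LHCB1.1, LHCB1.2, LHCB1.3, LHCB1.5, LHCB2.2 and the Rubisco genes RBCS1B, RBCS2B and RBCS3B. A further 14 were dropped because the reference table gave their locus another name, and 525 were tested. LHCB1.4, the only measured LHCB1 gene of the lists, was named in place of LHCB1.1, and its values need not hold for the others. The lists cover mitosis, DNA replication, endocycle and cell cycle inhibitors, proliferation promoting and restricting regulators, cell wall loosening, light harvesting complex, photosystem and electron transport subunits, Calvin cycle, tetrapyrrole and carotenoid biosynthesis, plastid transcription and ribosome, plastid division and import, chloroplast regulators, cytosolic ribosome and nucleolus, ABA, auxin and cytokinin response, oxidative stress, anthocyanin, carbon starvation, jasmonate and wounding, the circadian clock, and markers of stomatal lineage, guard cell, trichome, epidermis, vasculature, and shoot meristem and organ boundary.

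Lists were tested with camera at a preset correlation of 0.01 over 10 contrasts (290 tests, adjusted together). Camera with an estimated correlation per list and fry, whose directional p tests whether the genes of a list move one way on balance and whose mixed p tests for change in either direction, were run as alternatives. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of 1 list in 1 contrast. The effect of norflurazon at day 10 and the change in control leaves were each compared with the time course interval of days 9 to 10 by Pearson correlation across genes, with a jackknife over arrays for its error, and by Fisher's exact tests of the overlap of calls. Leaving out 1 array kept the rest of the fit. Other alternatives were the replicate block, quantile normalization again, median centring, filters at percentiles 25 and 50 of all values, eBayes with trend and robust options, a change of at least 1 log2, an adjusted p under 0.01, only the compared groups in the fit, and all 30 arrays in 1 fit. Regrouping tests used all 10 splits of 6 arrays into 3 and 3, or 100 drawn splits. For the interaction, treatment was reassigned within each day, and in a test added later the groups were reassigned over the 12 arrays after the additive effects of day and treatment were removed from each gene.

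The fits were tested on simulated data of 30237 genes with known changes. Changes of 0.5, 1 and 2 log2 were recovered in 35.6%, 83.6% and 98.8% of genes for day 10 minus day 9, 35.7%, 88.7% and 100.0% for the F test, 52.4%, 92.1% and 98.4% for norflurazon at day 9, and 42.9%, 93.6% and 100.0% for norflurazon at day 10. For the interaction they were 17.4%, 68.9% and 96.5%, and for the control leaves between days 9 and 10 they were 40.3%, 90.7% and 100.0%. In the list test the moved list was called and 0 of 28 unmoved lists were. The simulated noise was drawn independently for each gene, so this test cannot show false list calls that come from correlation between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.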

Results

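Transcripts of leaf 3 of Arabidopsis thaliana Col-0 seedlings were measured on 30 AGRONOMICS1 tiling arrays, in 10 groups of 3. A time course of untreated plants held 18 arrays, 3 for each day from 8 to 13 days after stratification, the cold treatment that synchronizes germination. A second experiment held 12 arrays. Its seedlings were given norflurazon or not at day 8 and were sampled 24 h later, on day 9, or 48 h later, on day 10. Norflurazon is a herbicide that inhibits phytoene desaturase, the carotenoid biosynthesis enzyme encoded by PDS3, and so damages chloroplasts in the light. The array medians were 3.5 to 3.63 (log2) in the time course and 2.81 to 2.88 in the norflurazon experiment. Arrays of 1 group correlated at 0.976 to 0.987 in the time course and at 0.992 to 0.995 in the norflurazon experiment. The number of arrays limits the precision. Changes are log2 differences between means of 3 arrays each, ± the standard error of the limma fit, and a called gene is 1 of 30237 probe sets with an adjusted p under 0.05. The table gives no detection call. Where the mean of the dimmer group lies at or below the median of its arrays, signal near background limits the change, and it is given as a lower limit of its size. The p-values measure the spread between arrays, which the labels call biological repeats.

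From day 8 to day 13, 29 of 32 mitosis genes and 21 of 21 genes of cytosolic ribosome and nucleolus fell, and 29 of 29 photosystem subunits and 14 of 17 vasculature markers rose (adjusted p = 0.127, 0.174, 0.199 and 0.0635 with an estimated correlation). CYCB1;2 (AT5G06150), a B-type cyclin, changed by -3.08 ± 0.22 and CDC20.2 (AT4G33260), an activator of the anaphase-promoting complex, by -3.21 ± 0.35. The replication clamp PCNA1 (AT1G07370) changed by -2.49 ± 0.14 and the histone H3 gene HTR13 (AT5G10390) by -2.39 ± 0.13. The growth regulators AN3 (AT5G28640), CYP78A5 (AT1G13710), GRF5 (AT3G13960) and ANT (AT4G37750), which prolong proliferation in leaf primordia, changed by -3.85 ± 0.30, -3.37 ± 0.25, -2.85 ± 0.22 and -2.78 ± 0.18. The changes of CDC20.2, CYP78A5 and GRF5, dim at day 13, are lower limits of their size. The carbonic anhydrase genes CA1 (AT3G01500) and CA2 (AT5G14740) rose by 7.04 ± 0.48 and 6.47 ± 0.27 (adjusted p = 8.41e-09 and 2.53e-10). Of all probe sets, 10192 (33.7%) differed between days 8 and 13, 4204 higher and 5988 lower, and 9809 (32.4%) differed in a moderated F test over the 6 days.

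Among the largest changes, CP12-2 (AT3G62410), a regulator of the Calvin cycle, rose by 5.48 ± 0.35, the photorespiratory catalase CAT2 (AT4G35090) by 4.75 ± 0.28, and the gibberellin-regulated GASA6 (AT1G74670) by 6.22 ± 0.28. The expansins EXPA8 (AT2G40610) and EXPA1 (AT1G69530), which loosen cell walls, rose by 4.90 ± 0.29 and 3.12 ± 0.17. The cutinase gene CDEF1 (AT4G30140) changed by -8.13 ± 0.47, the plant defensin gene PDF1.5 (AT1G55010) by -6.28 ± 0.36, PRB1 (AT2G14580), of the pathogenesis-related proteins, by -5.95 ± 0.34, and the lipid transfer protein gene LTP2 (AT2G38530) by -5.93 ± 0.31. CDEF1, PDF1.5 and PRB1 stood at 2.68, 3.1 and 2.84 at day 13, under the array median of 3.62, and EXPA8 at 3.53 at day 8, under 3.58, so these 4 changes are lower limits of their size. KRP3 (AT5G48820) and SIM (AT5G04470), inhibitors of cyclin-dependent kinases, changed by -3.52 ± 0.28 and -1.43 ± 0.24, while SMR1 (AT3G10525), of the SIM family, rose by 2.52 ± 0.24. The phytoene desaturase gene PDS3 (AT4G14210) rose by 1.13 ± 0.17 and the photosynthesis regulator GLK1 (AT2G20570) by 2.36 ± 0.19. RBCS1A (AT1G67090), a Rubisco small subunit near the top of the scale on every day, gave -0.02 ± 0.32 (adjusted p = 0.968).

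Of 29 gene lists, 16 were called between days 8 and 13 by camera with a preset correlation. In the lists of cell division, 29 of 32 mitosis genes, 23 of 25 DNA replication genes and 16 of 19 proliferation promoting regulators fell and 0 rose, with the same counts adjusted over the list alone and adjusted p = 0.127 for each with an estimated correlation. All 21 genes of cytosolic ribosome and nucleolus fell (21 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation), among them the fibrillarin gene FIB2 (AT4G25630), at -1.93 ± 0.25. Photosystem and electron transport subunits rose in 29 of 29 cases, light harvesting complex genes in 16 of 16 and Calvin cycle genes in 16 of 17, with the same counts adjusted over the list alone (adjusted p = 0.199, 0.197 and 0.201 with an estimated correlation). Higher calls went to 24 of 31 tetrapyrrole genes (26 adjusted over the list alone, and 1 lower) and 18 of 22 carotenoid and isoprenoid genes (20), with adjusted p = 0.324 and 0.174 with an estimated correlation. Plastid transcription and ribosome had 20 of 30 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.517 with an estimated correlation).

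Markers of cell types moved apart between days 8 and 13. Of vasculature markers 14 of 17 rose, among them the phloem sucrose transporter SUC2 (AT1G22710) by 3.36 ± 0.18 and the xylem protease XCP2 (AT1G20850) by 3.80 ± 0.32 (adjusted p = 0.0635 for the list with an estimated correlation). Of guard cell markers 8 of 9 rose, with the myrosinase TGG1 (AT5G26000) at 4.0 ± 0.43 (adjusted p = 0.111 with an estimated correlation). Trichome regulators fell in 8 of 10 cases (1 higher and 8 lower adjusted over the list alone), with GL1 (AT3G27920) at -4.38 ± 0.19 (adjusted p = 0.127 with an estimated correlation). The values of GL1, dim at day 13, and XCP2, dim at day 8, are lower limits of their size. Auxin response genes (12 of 16 higher, 4 lower), anthocyanin and flavonoid genes (0 higher, 7 of 12 lower) and endocycle and cell cycle inhibitors (3 of 17 higher, 9 lower) were called with adjusted p = 0.362, 0.542 and 0.174 with an estimated correlation. Adjusted over the list alone, 10 endocycle genes were lower, and the counts of the vasculature, guard cell, auxin and anthocyanin lists were the same. Lists with no camera call counted, higher and lower, 13 and 9 of 35 for cell wall loosening, 8 and 2 of 19 for cytokinin response, and 7 and 2 of 16 for ABA response. They counted 6 and 3 of 16 for the circadian clock, 5 and 2 of 10 for chloroplast regulators, and 4 and 3 of 19 for plastid division and protein import. Further counts were 4 and 6 of 14 for the stomatal lineage, 3 and 6 of 12 for proliferation restricting regulators and 2 and 4 of 7 for epidermis. The rest were 2 and 4 of 22 for oxidative stress, 3 and 3 of 10 for jasmonate and wounding, 2 and 2 of 12 for carbon starvation, and 1 and 1 of 10 for shoot meristem and organ boundary. Adjusted over the list alone, these became 14 and 9 for cell wall loosening, 8 and 4 for cytokinin response, 7 and 3 for the clock, 3 and 7 for proliferation restricting regulators and 2 and 3 for carbon starvation, and the other 8 were the same. Over all 10 contrasts 132 of 290 list tests were called, against a median of 85 with the groups reassigned at random, and 1 of 290 held with an estimated correlation.

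**Figure D1:**
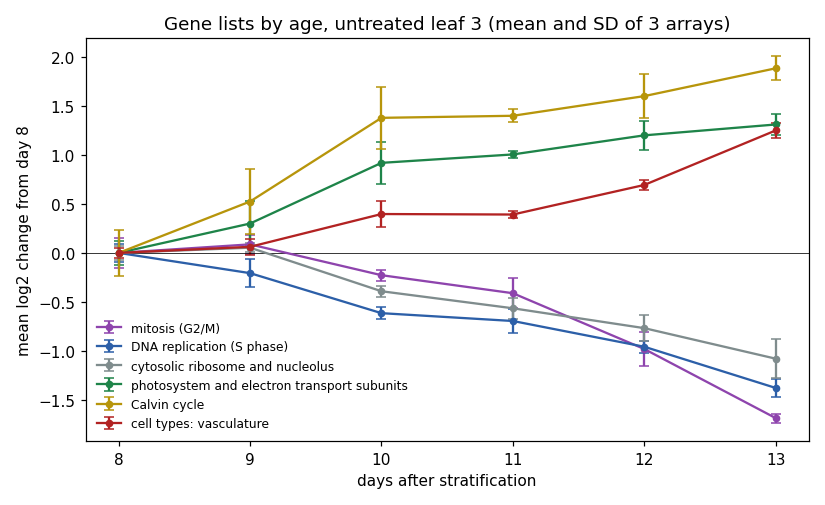
Mean log2 change from day 8 (y axis) against days after stratification (x axis) for 6 gene lists in the untreated time course, averaged over the members of each list; points are means and bars the SD of 3 arrays. By day 13 the mitosis list stood at -1.69 and the DNA replication list at -1.38, and the Calvin cycle list at 1.89.

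The 1-day intervals asked whether the changes came evenly. Between days 8 and 9 the carbonic anhydrases CA1 and CA2 already rose by 3.48 ± 0.48 and 2.94 ± 0.27 (adjusted p = 0.00118 and 4.99e-05), and the arabinogalactan protein gene FLA13 (AT5G44130) by 1.98 ± 0.27. The lipid transfer protein gene LTP3 (AT5G59320) changed by -3.76 ± 0.50, the metallothionein gene MT1C (AT1G07610) by -3.28 ± 0.53, and PDF1.5 by -2.48 ± 0.36. The protease inhibitor gene UPI (AT5G43580) changed by -2.45 ± 0.31, RRA1 (AT1G75120), an arabinosyltransferase of cell wall extensins, by -2.25 ± 0.29 and the jacalin lectin gene JAL33 (AT3G16450) by -2.22 ± 0.33. CYP78A5, a cytochrome P450 that promotes organ growth, changed by -2.17 ± 0.25, and ERL2 (AT5G07180), a receptor kinase of stomatal patterning, by -1.13 ± 0.19. GLK1 rose by 1.02 ± 0.19 (adjusted p = 0.0138, and up to 0.0935 without day 8 replicate 2).

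Chloroplast lists were called higher between days 8 and 9 with few of their genes past the test over all genes. Plastid transcription and ribosome counted 1 of 30 genes higher (19 adjusted over the list alone), tetrapyrrole biosynthesis 0 of 31 (14 adjusted over the list alone), the Calvin cycle 0 of 17 (13) and photosystem subunits 0 of 29 (8), with adjusted p = 0.174, 0.203, 0.230 and 0.352 with an estimated correlation. Light harvesting complex genes counted 1 of 16 (3 adjusted over the list alone), plastid division and import 1 of 19 (6), and carotenoid and isoprenoid genes 0 of 22 (0), with adjusted p = 0.265, 0.253 and 0.211 with an estimated correlation. Proliferation promoting regulators counted 1 of 19 lower (8 adjusted over the list alone) and DNA replication 1 of 25 (5), with adjusted p = 0.231 and 0.279 with an estimated correlation. LHCB1.4 (AT2G34430), a light harvesting protein of photosystem II, gave 1.02 ± 0.27 (adjusted p = 0.0782), CYCB1;1 (AT4G37490) 0.12 ± 0.14 (0.850) and ANT -0.70 ± 0.18 (0.0733). The interval held 386 called probe sets, 139 higher and 247 lower, or 299 higher and 261 lower after quantile normalization again. The count was 805 without day 8 replicate 1, 137 without replicate 2 and 159 without replicate 3 of that day, and 115 and 678 without day 9 replicates 2 and 3, and it was 16 with only the 6 compared arrays in the fit.

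Days 9 to 10 brought the largest number of calls of the 5 intervals. Of the lists, 26 of 29 photosystem subunits and 14 of 17 Calvin cycle genes rose, and 13 of 21 genes of cytosolic ribosome and nucleolus, 10 of 19 proliferation promoting regulators and 4 of 32 mitosis genes fell. None of these lists was called with an estimated correlation (adjusted p = 0.174, 0.174, 0.199, 0.127 and 0.352). LHCB1.4 and LHCB2.3 (AT3G27690) rose by 1.68 ± 0.27 and 1.43 ± 0.21, and CP12-2 by 2.25 ± 0.35. Rises also came from the fructose-1,6-bisphosphatase gene HCEF1 (AT3G54050), by 1.3 ± 0.26, the ferredoxin reductase gene FNR1 (AT5G66190), by 0.92 ± 0.17, the β-carotene hydroxylase gene BCH2 (AT5G52570), by 1.22 ± 0.20, CAT2, by 1.76 ± 0.28, and the jasmonate biosynthesis gene LOX2 (AT3G45140), by 2.24 ± 0.32. Of regulators of leaf proliferation, JAG (AT1G68480) changed by -1.28 ± 0.20, GRF5 by -1.26 ± 0.22 and ANT by -1.05 ± 0.18, and PPD2 (AT4G14720), which restricts the division of meristemoids, by -1.1 ± 0.18. PCNA1 changed by -0.75 ± 0.14 and the Aurora kinase gene AUR3 (AT2G45490) by -0.73 ± 0.14. The trichome regulators CPC (AT2G46410) and GL1 changed by -1.44 ± 0.24 and -1.35 ± 0.19, and the auxin conjugating GH3.3 (AT2G23170) by -1.18 ± 0.21.

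The genes with the largest rises between days 9 and 10 included several that respond to nutrient supply. LSU2 (AT5G24660), induced by low sulfur, rose by 3.2 ± 0.36 (adjusted p = 0.000540), and the phosphate responsive genes PAP17 (AT3G17790), an acid phosphatase, and SPX1 (AT5G20150), a phosphate sensor, by 2.84 ± 0.44 and 2.72 ± 0.45. ECS1 (AT1G31580) rose by 3.46 ± 0.44. CDEF1 changed by -3.2 ± 0.47, PRB1 by -3.07 ± 0.34, PDF1.5 by -3.05 ± 0.36, UPI by -2.15 ± 0.31, RRA1 by -1.66 ± 0.29 and the trypsin inhibitor gene TI1 (AT2G43510) by -1.49 ± 0.28. The changes of LSU2, dim at day 9, and of UPI and RRA1, dim at day 10, are lower limits of their size. Of the mitotic genes named in advance, KNOLLE (AT1G08560), the cytokinesis syntaxin, and CYCB1;1 did not pass, at -0.10 ± 0.16 (adjusted p = 0.811) and -0.37 ± 0.14 (0.115).

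By list, 26 of 29 photosystem subunits (28 adjusted over the list alone), 14 of 17 Calvin cycle genes (15) and 10 of 16 light harvesting genes (15) rose between days 9 and 10, each with adjusted p = 0.174 with an estimated correlation. Fewer members rose of tetrapyrrole biosynthesis, 5 of 31 (11 adjusted over the list alone), carotenoid and isoprenoid biosynthesis, 5 of 22 (10), and plastid transcription and ribosome, 5 of 30 (13, and 1 lower), with adjusted p = 0.262, 0.227 and 0.502 with an estimated correlation. Of cytosolic ribosome and nucleolus 13 of 21 fell (21 adjusted over the list alone), of DNA replication 11 of 25 (20), of proliferation promoting regulators 10 of 19 (13) and of mitosis 4 of 32 (11), with adjusted p = 0.199, 0.174, 0.127 and 0.352 with an estimated correlation. Trichome regulators fell in 4 of 10 cases (5 adjusted over the list alone), and vasculature and guard cell markers rose in 3 of 17 (5) and 2 of 9 (5), with adjusted p = 0.127, 0.127 and 0.174 with an estimated correlation. In all, 2232 probe sets (7.38%) were called, 718 higher and 1514 lower, or 1106 higher and 952 lower after quantile normalization again. Of the calls with a change of at least 1 log2, 196 were higher and 93 lower. The count was 749 without day 9 replicate 3, 753 without day 10 replicate 2 and 1036 without day 10 replicate 3, and 704 with only the compared arrays in the fit.

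Between days 10 and 11 no gene was called by limma, and 2156 probe sets, 1282 higher and 874 lower, had an unadjusted p under 0.05, the smallest adjusted p being 0.0620. The genes named in advance gave small values, such as EXPA1 at 0.58 ± 0.17 (adjusted p = 0.472), GLK1 at 0.52 ± 0.19 (0.588), KNOLLE at -0.31 ± 0.16 (0.736), CYCB1;1 at -0.30 ± 0.14 (0.687) and LHCB1.4 at 0.14 ± 0.27 (0.968). As lists, mitosis, DNA replication and cytosolic ribosome were called lower with 0 called members, over all genes and adjusted over the list alone (adjusted p = 0.276, 0.602 and 0.373 with an estimated correlation). The DNA replication call ended without day 11 replicate 3 (adjusted p = 0.465). Without day 10 replicate 1 the interval held 2 called genes, without day 10 replicate 3 also 2, and without day 11 replicate 2 it held 6.

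**Figure D2:**
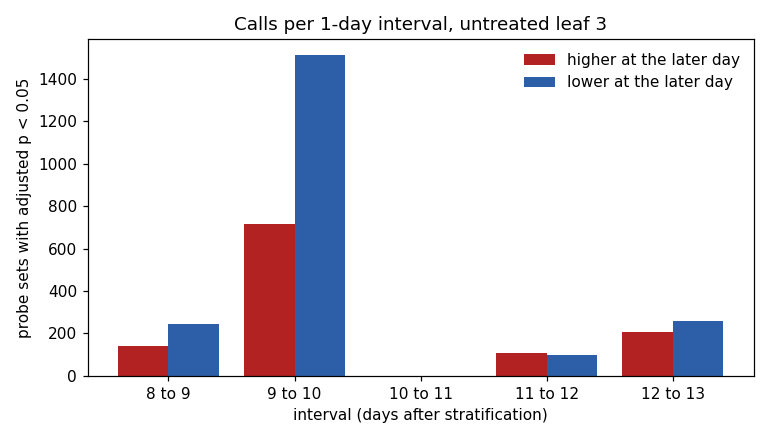
Number of probe sets called higher (left bars) and lower (right bars) in each 1-day interval of the untreated time course, 3 arrays per day. The bars count 139 and 247 for days 8 to 9, 718 and 1514 for days 9 to 10, 0 and 0 for days 10 to 11, 110 and 100 for days 11 to 12, and 206 and 259 for days 12 to 13.

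From day 11 to day 12, 9 of 32 mitosis genes fell. KNOLLE changed by -0.74 ± 0.16, CYCB1;1 by -0.66 ± 0.14, CYCB1;4 (AT2G26760) by -0.95 ± 0.17 and the Aurora kinase gene AUR2 (AT2G25880) by -0.83 ± 0.18, and the histone H3 gene HTR3 (AT3G27360) changed by -0.49 ± 0.09. PAP8 (AT2G01890) and the auxin responsive SAUR23 (AT5G18060) rose by 1.67 ± 0.19 and 1.29 ± 0.15 (adjusted p = 0.00386 each). GASA6 rose by 1.77 ± 0.28 and EXPA8 by 1.54 ± 0.29, whereas SPX1 changed by -2.50 ± 0.45, the phosphate responsive SRG3 (AT3G02040) by -2.75 ± 0.50 and GL1 by -1.25 ± 0.19. Of these 12 genes PAP8 and SAUR23 kept their calls with any 1 array of either day left out. The other 10 lost theirs without day 12 replicate 3 or day 11 replicate 2, with highest adjusted p from 0.0636 for GL1 to 0.233 for KNOLLE without day 12 replicate 3. Of the mitosis genes 27 fell adjusted over the list alone, of 25 DNA replication genes 2 over all genes (11 over the list alone) and of 19 proliferation promoting regulators 0 (5), with adjusted p = 0.111, 0.197 and 0.200 with an estimated correlation. Vasculature markers were called higher as a list with 0 of 17 genes called (6 adjusted over the list alone), and anthocyanin and flavonoid genes lower with 1 of 12 (7), with adjusted p = 0.127 and 0.211 with an estimated correlation. The interval held 210 called probe sets, 110 higher and 100 lower. It held 29 and 10 without day 11 replicates 1 and 2, and 93 and 17 without day 12 replicates 1 and 3, and 3 with only the compared arrays in the fit.

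From day 12 to day 13, 14 of 32 mitosis genes fell and 8 of 17 vasculature markers rose. CYCB1;2 changed by -1.32 ± 0.22, KNOLLE by -1.13 ± 0.16, and the histone H3 genes HTR9 (AT5G10400) and HTR3 by -0.96 ± 0.11 and -0.92 ± 0.09 (adjusted p = 0.000663 and 0.000200). LTP2 changed by -2.43 ± 0.31, E13L3 (AT5G08000), a callose-binding protein gene, by -1.79 ± 0.24, and AGP31 (AT1G28290), an arabinogalactan protein gene, by -1.59 ± 0.23. RL4 (AT2G18328), of the RADIALIS-like MYB family, rose by 1.94 ± 0.22, XTH7 (AT4G37800), a xyloglucan endotransglucosylase, by 1.54 ± 0.24 and the phloem transporter SUC2 by 1.43 ± 0.18 (adjusted p = 0.000843). AN3 fell by 1.37 ± 0.30 (adjusted p = 0.0322, and up to 0.173 without day 12 replicate 2) and XCP2 rose by 1.45 ± 0.32 (0.0322, and up to 0.125 without day 12 replicate 1). EXPA1 rose by 0.78 ± 0.17 (0.0298, and up to 0.142 without day 12 replicate 2).

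Of 17 vasculature markers 8 rose between days 12 and 13 (11 adjusted over the list alone), with camera adjusted p = 1.28e-13 and adjusted p = 0.0318 with an estimated correlation. Mitosis genes fell in 14 of 32 cases (26 adjusted over the list alone), DNA replication genes in 7 of 25 (12), proliferation promoting regulators in 4 of 19 (9) and cytosolic ribosome genes in 0 of 21 (12), with adjusted p = 0.111, 0.127, 0.174 and 0.218 with an estimated correlation. Auxin response genes rose in 4 of 16 cases (9 adjusted over the list alone), cell wall loosening genes in 4 of 35 beside 1 lower (11 and 2), and ABA response genes in 0 of 16 (4), with adjusted p = 0.127, 0.127 and 0.209 with an estimated correlation. The interval held 465 called probe sets, 206 higher and 259 lower. Without day 12 replicates 1, 2 and 3 it held 158, 122 and 770, and without day 13 replicates 1 and 2 it held 279 and 167, and with only the compared arrays in the fit 2. Of the mean rise of the 4204 genes higher at day 13 than at day 8, the 5 intervals in order of age carried 17.3%, 28.2%, 11.1%, 20% and 23.3%, and of the mean fall of the 5988 lower genes 13.8%, 38.0%, 7.0%, 18.2% and 23.0%.

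The norflurazon comparisons asked how a block of carotenoid synthesis changes the transcripts of the young leaf. After 24 h, genes of cell division, photosynthesis, anthocyanin and jasmonate were among those higher in treated than in control leaves, and 4 of 12 carbon starvation genes were lower. PORB (AT4G27440), a protochlorophyllide oxidoreductase, was higher by 2.18 ± 0.18. The anthocyanin genes DFR (AT5G42800), GSTF12 (AT5G17220) and PAP1 (AT1G56650) were higher by 2.05 ± 0.26, 1.81 ± 0.27 and 1.48 ± 0.21, the ethylene biosynthesis gene ACS6 (AT4G11280) by 1.68 ± 0.16 and the zinc finger gene SZF1 (AT3G55980) by 1.82 ± 0.22. SEN1 (AT4G35770), induced in darkness and senescence, was lower at -4.61 ± 0.36 (adjusted p = 7.22e-05), BT2 (AT3G48360), a BTB and TAZ domain protein gene repressed by sugar, at -2.52 ± 0.26, and the alternative oxidase gene AOX1A (AT3G22370) at -1.20 ± 0.12. The control arrays of day 9 stood apart from the other 9 arrays of this experiment on the first principal component (31.7% of the variance), at -39.0 to -27.6 against -0.4 to 18. SEN1 stood at 6.98 to 8.83 in the control leaves of day 9 and at 2.68 to 4.39 in the other 9 arrays. An exchange of the labels of the control and norflurazon samples of day 9 is not excluded. It would turn the sign of every effect given here for day 9, with 1159 probe sets higher and 1089 lower.

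Division genes higher at day 9 included PCNA1 at 1.13 ± 0.12, CYCB1;2 at 0.91 ± 0.10, KNOLLE at 0.90 ± 0.14, HTR3 at 0.71 ± 0.11 and ANT at 0.80 ± 0.16. From the list of endocycle and cell cycle inhibitors, KRP3 was higher at 0.84 ± 0.15 and CCS52B (AT5G13840) at 0.73 ± 0.10. Photosynthesis and pigment genes higher were LHCB1.4 at 1.47 ± 0.12, the plastocyanin gene PETE1 (AT1G76100) at 1.17 ± 0.09, PSBQ2 (AT4G05180), of the oxygen-evolving complex, at 1.11 ± 0.17, HEMC (AT5G08280) at 0.93 ± 0.09 and the phytoene synthase gene PSY (AT5G17230) at 0.66 ± 0.12. Among called light harvesting genes the next largest effect after LHCB1.4 was 0.82 ± 0.10, for LHCB4.2 (AT3G08940). Further higher genes were ERF6 (AT4G17490), an ethylene response factor, at 1.3 ± 0.21, the calmodulin-like TCH3 (AT2G41100) at 1.05 ± 0.20, GH3.3 at 1.01 ± 0.14 and the jasmonate gene AOS (AT5G42650) at 0.78 ± 0.11. SPL3 (AT2G33810) was lower at -1.99 ± 0.19, CRF6 (AT3G61630), a cytokinin response factor, at -1.83 ± 0.19 and the light signalling factor HY5 (AT5G11260) at -0.73 ± 0.12. The transcript of the target enzyme, PDS3, gave 0.02 ± 0.08 (adjusted p = 0.925).

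By list, 21 of 32 mitosis genes (28 adjusted over the list alone) and 12 of 25 DNA replication genes (17) were higher at day 9, with adjusted p = 0.111 and 0.127 with an estimated correlation. Higher calls also went to 20 of 29 photosystem subunits (25 adjusted over the list alone), 15 of 31 tetrapyrrole genes (21, and 1 lower), 11 of 17 Calvin cycle genes (13) and 10 of 16 light harvesting genes (11, and 1 lower), with adjusted p = 0.174, 0.174, 0.204 and 0.196 with an estimated correlation. Jasmonate and wounding genes were higher in 6 of 10 cases (6 adjusted over the list alone) and anthocyanin genes in 5 of 12 (5), and carbon starvation genes lower in 4 of 12 (6), with adjusted p = 0.174, 0.197 and 0.127 with an estimated correlation. Oxidative stress genes, 7 of 22 higher and 4 lower, were not called as a list. Of the probe sets 2248 were called, 1089 higher and 1159 lower. The count was 1427 and 1416 without norflurazon day 9 replicates 1 and 2, and 1492 without control day 9 replicate 3.

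**Figure D3:**
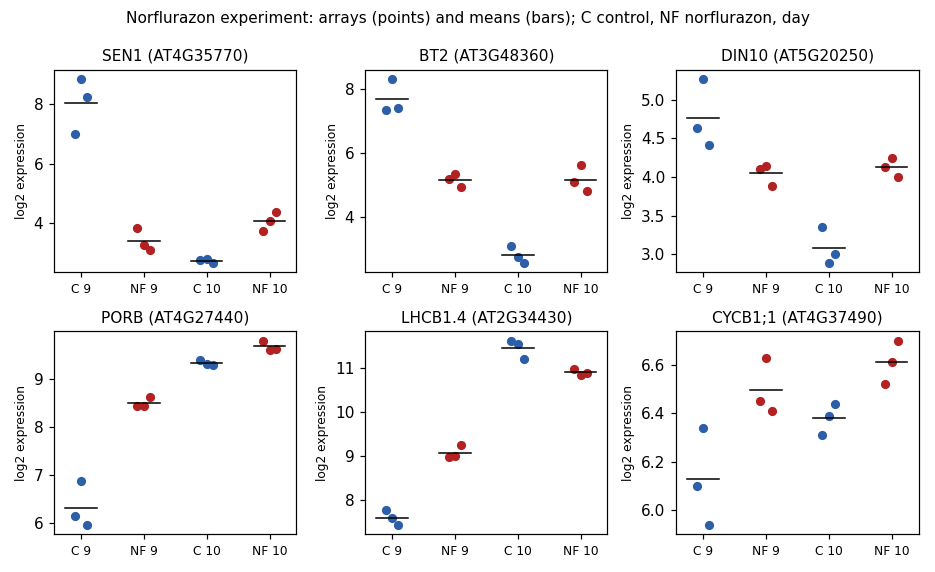
Log2 level (y axis) of SEN1, BT2, DIN10, PORB, LHCB1.4 and CYCB1;1 in the 4 groups of the norflurazon experiment (C control, NF norflurazon, at day 9 or 10); points are the 3 arrays and bars their mean. SEN1, BT2 and DIN10 were highest in the control leaves of day 9, where PORB and LHCB1.4 were lowest.

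After 48 h fewer probe sets differed, 233 against 2248 after 24 h. BT2 was higher in treated leaves by 2.36 ± 0.26 (adjusted p = 0.00604) and APR1 (AT4G04610), an adenylylsulfate reductase of sulfate assimilation, lower at -1.36 ± 0.14 (0.00461), and both calls held with any 1 of the 6 arrays left out. BT2 stood at 2.81 in control leaves and bHLH39 at 2.1 in treated leaves, under array medians of 2.84 and 2.82, so both effects are lower limits of their size. ECS1 was lower at -2.31 ± 0.28, LSU2 at -1.95 ± 0.33, and the sulfate assimilation genes APR3 (AT4G21990) and APR2 (AT1G62180) at -1.20 ± 0.23 and -1.04 ± 0.18. Lower too were bHLH39 (AT3G56980), an iron deficiency regulator, at -1.13 ± 0.17, LOX2 at -0.94 ± 0.17, CAT2 at -0.85 ± 0.17 and GLK1 at -0.75 ± 0.14. Higher were UPI at 1.57 ± 0.30, BT5 (AT4G37610) at 1.53 ± 0.22, LBD41 (AT3G02550) at 1.31 ± 0.23, MT1C at 1.26 ± 0.21 and DIN10 (AT5G20250), a dark-induced gene, at 1.04 ± 0.19. So were EXPA3 (AT2G37640) at 0.84 ± 0.12, the ferritin gene FER1 (AT5G01600) at 0.70 ± 0.12, GH3.3 at 0.70 ± 0.14 and GL1 at 0.63 ± 0.10. Each of these 17 genes lost its call with 1 array or more of the 6 left out, and for 11 of them the adjusted p was highest without control day 10 replicate 2. The highest values ran from 0.0522 for ECS1 without that array to 0.146 for CAT2 without norflurazon day 10 replicate 3. PDS3 gave -0.10 ± 0.08 (adjusted p = 0.625), LHCB1.4 -0.55 ± 0.12 (0.0651) and KNOLLE 0.34 ± 0.14 (0.293).

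Lists at day 10 were called with few called members. Photosystem subunits were lower with 0 of 29 called (10 adjusted over the list alone), light harvesting genes with 0 of 16 (10), Calvin cycle genes with 0 of 17 (8) and carotenoid genes with 0 of 22 (4), with adjusted p = 0.290, 0.220, 0.203 and 0.200 with an estimated correlation. Guard cell markers were lower with 0 of 9 called (3 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). Mitosis genes were higher with 0 of 32 called (6 adjusted over the list alone), proliferation promoting regulators with 0 of 19 (6, and 1 lower), cytosolic ribosome genes with 0 of 21 (0) and oxidative stress genes with 1 of 22 beside 1 lower (9 and 1), with adjusted p = 0.211, 0.358, 0.265 and 0.408 with an estimated correlation. Trichome regulators were higher with 1 of 10 called (4 adjusted over the list alone; adjusted p = 0.174 with an estimated correlation). Of the probe sets 233 were called, 120 higher and 113 lower, or 113 higher and 210 lower after quantile normalization again. The count was 68, 23 and 79 without norflurazon day 10 replicates 1, 2 and 3, and 57, 16 and 114 without control day 10 replicates 1, 2 and 3.

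The effect of norflurazon differed between the days for 589 probe sets in the test of the interaction, 381 with a higher and 208 with a lower effect at day 10 (358 and 335 after quantile normalization again). For BT2 the effect went from -2.52 to 2.36 (difference 4.87 ± 0.37, adjusted p = 0.000252) and for SEN1 from -4.61 to 1.32 (difference 5.93 ± 0.52, 0.000285). Both genes were dim in control leaves of day 10, at 2.81 and 2.75, so these differences and the effect of BT2 at day 10 are lower limits of their size. The effect of SEN1 at day 10 was not called (adjusted p = 0.118). For LHCB1.4 the effect went from 1.47 to -0.55 (difference -2.02 ± 0.17), and for GLK1 from 0.40 to -0.75 (difference -1.15 ± 0.20). Not called were the effects of LHCB1.4 at day 10 (adjusted p = 0.0651) and of GLK1 at day 9 (0.125). The difference was -1.43 ± 0.13 for PETE1, -1.03 ± 0.12 for HEMC, -0.94 ± 0.17 for PSY, -2.08 ± 0.37 for DFR and -1.14 ± 0.16 for AOS. AOX1A went the other way, from -1.20 to -0.10 (difference 1.1 ± 0.17). Of the list members 16 of 29 photosystem subunits, 12 of 31 tetrapyrrole genes, 10 of 16 light harvesting genes and 7 of 17 Calvin cycle genes had a lower effect at day 10 (adjusted p = 0.0621 for each list with an estimated correlation). The control arrays of day 9, which stood apart, enter each of these differences, and with the labels of day 9 exchanged the count would be 2190. The count was 387 without norflurazon day 9 replicate 1, 365 and 392 without norflurazon day 10 replicates 2 and 3, and 359 without control day 10 replicate 2.

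Control leaves of this experiment changed from day 9 to day 10 in 3474 probe sets, 1567 higher and 1907 lower. The interval starts from the control arrays of day 9, which stood apart from the other 9 arrays of the experiment. Relative to them the mean of the mitosis list was 0.436 in control leaves of day 10, and 0.510 and 0.635 in treated leaves of days 9 and 10. For carbon starvation the means were -0.881, -0.658 and -0.679. LHCB1.4 rose by 3.84 ± 0.12 (adjusted p = 3.09e-08), PORB by 3.02 ± 0.18, GLK1 by 2.57 ± 0.14, the vegetative storage protein gene VSP2 (AT5G24770) by 2.42 ± 0.27 and CA1 by 2.32 ± 0.37. Among called light harvesting genes the next largest change after LHCB1.4 was 1.63 ± 0.10, for LHCB4.2. SEN1 changed by -5.26 ± 0.36 and BT2 by -4.87 ± 0.26. The small heat shock protein gene HSP17.6A (AT5G12030) changed by -3.05 ± 0.45, DYL1 (AT1G28330) by -3.00 ± 0.20, SAG21 (AT4G02380), linked to senescence, by -2.75 ± 0.20 and the superoxide dismutase gene CSD2 (AT2G28190) by -1.99 ± 0.10. The changes of SEN1, BT2 and HSP17.6A, dim at day 10, are lower limits of their size. By list, 28 of 29 photosystem subunits (28 adjusted over the list alone), 14 of 16 light harvesting genes beside 1 lower (14 and 1), 21 of 31 tetrapyrrole genes beside 1 lower (25 and 2) and 15 of 17 Calvin cycle genes (16) rose, each with adjusted p = 0.127 with an estimated correlation. Mitosis genes rose in 21 of 32 cases (26 adjusted over the list alone), jasmonate genes in 6 of 10 (9) and stomatal lineage genes in 5 of 14 (6), and carbon starvation genes fell in 7 of 12 (8), with adjusted p = 0.127, 0.127, 0.111 and 0.127 with an estimated correlation. With norflurazon day 9 in place of control day 9 as the start of the interval, as an exchange of their labels would have it, 1510 probe sets were called, 853 higher and 657 lower.

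Treated leaves changed from day 9 to day 10 in 594 probe sets, 499 higher and 95 lower. With the labels of day 9 exchanged, the interval would start from the arrays labelled control, with 3976 probe sets called, 2244 higher and 1732 lower. LHCB1.4 rose by 1.81 ± 0.12, VSP2 by 1.68 ± 0.27, GLK1 by 1.42 ± 0.14, BGLU44 (AT3G18080) by 1.28 ± 0.12, PORB by 1.18 ± 0.18, PORA (AT5G54190) by 0.99 ± 0.16 and XTH16 (AT3G23730) by 0.93 ± 0.13. The change of PORA, dim at day 9, is a lower limit of its size. The early light-inducible genes ELIP1 (AT3G22840) and ELIP2 (AT4G14690) changed by -2.08 ± 0.25 and -1.86 ± 0.28, and CSD2 by -0.91 ± 0.10. Light harvesting genes rose in 6 of 16 cases (12 adjusted over the list alone, and 1 lower) and cell wall loosening genes in 6 of 35 (8), with adjusted p = 0.174 and 0.0997 with an estimated correlation. KNOLLE gave 0.11 ± 0.14 (adjusted p = 0.860). The count was 311, 340 and 331 without norflurazon day 9 replicates 1, 2 and 3, and 306, 259 and 340 without norflurazon day 10 replicates 1, 2 and 3.

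Genes that changed with norflurazon at day 10 moved against their change from day 9 to day 10 in the untreated time course, which shares no array with that contrast. Of the 113 genes lower with norflurazon, 78 had risen with age and 0 had fallen, and of the 120 higher genes 47 had fallen and 0 had risen, where 2.7 and 6.0 were expected by chance for the shared genes (Fisher's exact test, two-sided, p = 2.58e-100 and 6.3e-30). ECS1, LSU2, CAT2, LOX2 and bHLH39 were among the former and UPI, GH3.3 and GL1 among the latter. Over all genes the effect of norflurazon at day 10 correlated with the change from day 9 to day 10 at r = -0.557 (jackknife SE over arrays 0.074), and at -0.592 with the change from day 8 to day 13. Genes are not independent replicates, so the correlations carry no p and the Fisher p is a description of the overlap.

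**Figure D4:**
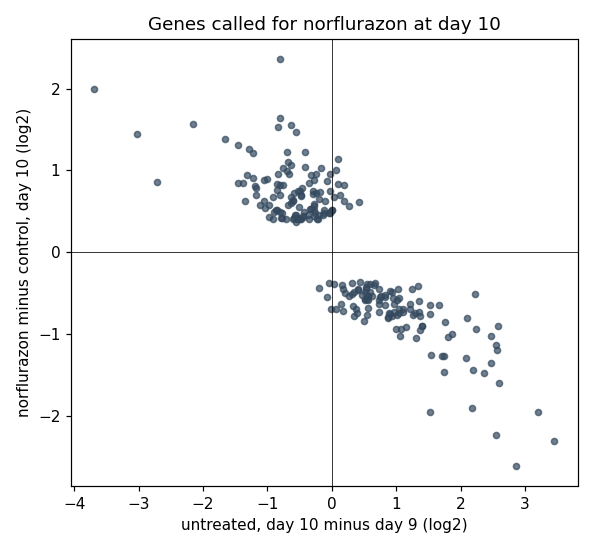
The 233 genes called between norflurazon and control at day 10, with the log2 change from day 9 to day 10 in the untreated time course (x axis) and the log2 effect of norflurazon at day 10 (y axis). Of the 233 genes 220 had opposite signs on the axes.

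The control leaves and the time course covered days 9 to 10 with separate arrays, and their changes correlated across genes at r = 0.227 (jackknife SE 0.110). Genes higher in both numbered 284 against 37.2 expected and genes lower in both 245 against 95.5 (Fisher's exact test, two-sided, p = 1.3e-177 and 7.72e-44). Genes are not independent replicates, so the Fisher p is a description of the overlap. Of 10 splits of the control arrays, 4 gave a correlation with the time course at least as large in size, the real one included. The highest other had a size of 0.361, so chance is not excluded for this correlation. Genes higher in the control leaves and lower in the time course numbered 82 against 78.5 expected, and those lower and higher 28 against 45.3. Of all genes 54.2% had the same sign in both, and of the 3474 called in the control leaves 1267 had the opposite sign in the time course. LHCB1.4 rose in both, by 3.84 ± 0.12 and 1.68 ± 0.27, and LOX2 by 1.57 ± 0.17 and 2.24 ± 0.32. PCNA1 rose by 0.95 ± 0.12 in the control leaves and fell by 0.75 ± 0.14 in the time course. In a single fit of all 30 arrays the changes of the 2 experiments differed for 2058 probe sets. In the control leaves 21 of 32 mitosis and 16 of 25 DNA replication genes had a higher change and 4 of 12 carbon starvation genes a lower one. So had 5 of 17 endocycle and cell cycle inhibitors and 4 of 14 stomatal lineage genes a higher change (adjusted p = 0.0335 for each of these lists with an estimated correlation). The control arrays of day 9, at -39.0 to -27.6 on the first principal component against -0.4 to 18 for the other 9 arrays of their experiment, enter each of these values. Starting the interval from norflurazon day 9 instead, a choice made after the results were seen, gave r = 0.509. The difference also includes any difference between the experiments in growth, harvest and array processing, so it is not shown to be one of development.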

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

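Chosen after the results were seen were both tests of the control arrays of day 9, the test of an outlying day 10 array, the test of the interaction with day and treatment effects removed, the list tests of the interaction, the clock score and the comparison of the experiments.

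The effect of norflurazon differed between days 9 and 10 for 589 probe sets. Of 100 reassignments of treatment within each day 2 gave as many genes, the real one included, and the highest other gave 609. That split kept the treatment of all 6 arrays of day 9 and of 2 of the 6 of day 10, so the count can be reached without the labels of day 10, and these splits are not a test of the interaction alone. With the additive effects of day and treatment removed from each gene first, 1 of 100 reassignments of the 12 arrays gave as many, the real one, and the highest other gave 4, so chance is excluded. A difference of the control arrays of day 9 for another reason is not. The differences of SEN1, BT2, NAC044 and LUX, dim in control leaves of day 10, are lower limits of their size. The named genes with a higher effect at day 10 were SEN1 (difference 5.93), BT2 (4.87), SAG21 (2.23), DYL1 (2.18), J8 (2.12), NAC044 (1.91), CRF6 (1.85), DIN10 (1.76), AOX1A (1.1), CSD2 (1.08), HY5 (0.94), XTH28 (0.70), LUX (0.70) and AFP1 (0.66). Photosynthesis genes with a lower effect were LHCB1.4 (-2.02), PETE1 (-1.43), PSBQ2 (-1.30), HCEF1 (-1.20), LHCB4.2 (-1.03) and FBA1 (-0.87). Pigment and plastid genes with a lower effect were PORB (-1.83), GLK1 (-1.15), HEMC (-1.03), PSY (-0.94), GGPS1 (-0.66), HEMA1 (-0.64), FTSZ2-2 (-0.63) and GUN4 (-0.54). Further genes with a lower effect were DFR (-2.08), PAP1 (-1.78), GSTF12 (-1.77), APR1 (-1.69), AOS (-1.14), COL2 (-0.97), TCP10 (-0.86), PCNA1 (-0.85), HTR3 (-0.73) and CRF2 (-0.49). Of these 38 genes 28 kept the call with any 1 of the 12 arrays left out.

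The changes from day 9 to day 10 in the control leaves and in the time course differed for 2058 probe sets, 1333 higher and 725 lower in the control leaves, in arrays that differ by experiment as well, and the control arrays of day 9 enter the difference.

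The control arrays of day 9 stood apart from the other 9 arrays of their experiment. An exchange of the labels of the control and norflurazon samples of day 9 cannot be told apart from correct labels. Against an exchange, 68.2% of the 233 genes called at day 10 had the same sign at day 9 (63.5% to 68.7% with 1 array left out) and the effects of both days correlated at 0.210 (0.125 to 0.261), and for it, control day 10 minus norflurazon day 9 followed the time course interval at r = 0.509, more than control day 10 minus control day 9 at 0.227. The condition on the time course was added after the first values of this test were seen, and without it the values would have counted against an exchange. It stays open because the effects of norflurazon need not have the same sign on both days. The second principal component (16.6% of the variance), read after the results were seen, also counts against an exchange without excluding it. As labelled it was higher in treated leaves, at 11.4 to 21.6 on day 9 and 5.9 to 9.4 on day 10. In control leaves it stood at -17.6 to 4.1 and -21.2 to -18.2. With the labels exchanged, treated and control leaves would overlap on it. For a state like carbon starvation in the control plants of day 9, 83.3% of the list (10 of 12 genes) were highest there. The list had already been called in both comparisons with this group, so the share restates those calls and decides nothing. Effects of norflurazon at day 9 rest on this group, and why it stood apart stays open.

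Genes changed by norflurazon at day 10 ran against their change with age. Differences left between array distributions are not the whole cause, since r was -0.535 after quantile normalization again (-0.546 to -0.468 with 1 array left out). The deposited values were already quantile normalized and no other method was tried on r, so an effect of normalization is not excluded. Nor are the 241 probe sets of the plastid lists and plastid-encoded genes the whole cause, since r was -0.555 without them (-0.565 to -0.492). Other nuclear genes of plastid proteins stayed in, such as NdhN and NdhU, so plastid genes in general are not excluded. Of 8136 genes called between days 8 and 13 but not between days 9 and 10, 81.6% moved against their change with age (78.6% to 82.2%). This is what slower leaf development under norflurazon would give, as a hypothesis found and tested on the same arrays. A difference in harvest time stays open beside it, since the clock score, evening minus morning genes, differed by 0.62 between the treated and control leaves of day 10, and the score also moves with age. Other differences between control and treated plants were not tested.

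No gene was called between days 10 and 11. An outlying day 10 array found no support as the cause, since at most 2 genes were called with any 1 of these arrays left out. Leaving out an array also lowers the power, so this does not exclude such an array. A change as large as in other intervals but hidden by the spread between arrays found no support. The variance of the log2 change across genes, less its error, was 0.0105 (0.0045 to 0.0155 with 1 array left out). It was 0.0359, 0.0665, 0.0287 and 0.0345 in the intervals before and after it in order of age. Only arrays of days 10 and 11 were left out and no error was computed for these variances, so such a change is not excluded. A slower change of the leaf between these days stays open and was not tested otherwise.

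For the other comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The called genes in the real split and the highest other were 386 and 2 for days 8 to 9, 2232 and 1 for days 9 to 10, 0 and 0 for days 10 to 11 (10 of 10 splits as large), 210 and 1 for days 11 to 12, 465 and 1 for days 12 to 13, and 10192 and 0 for days 8 to 13. They were 2248 and 0 for norflurazon at day 9, 233 and 0 at day 10, 3474 and 1 for the control leaves and 594 and 0 for treated leaves between days 9 and 10. The size of the correlation was 0.557 against 0.382 for norflurazon with the change with age (1 of 10 splits as large), and 0.227 against 0.361 for the control leaves with the time course (4 of 10). Chance is excluded for the F test over ages, with 9809 genes against 16 in the highest other of 100 splits (1 as large). For the number of list calls the real groups gave 132 and the highest other split 137 (2 of 100 as large, the real one included). Few splits gave as many list calls, but 1 gave more, so chance is not excluded there. The other splits gave a median of 85 list calls, so a single list call with the preset correlation is weak evidence.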

How the results depend on the processing

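The interval that starts at norflurazon day 9 in place of control day 9, the exchange of the labels of day 9 and the norflurazon effect at day 9 set against age were chosen after the results were seen.

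No named gene and no list changed direction while called under the settings in which genes and lists were scored. The exchange of the day 9 labels was not scored by gene or list, and it turns the sign of every norflurazon effect at day 9. The mixed p of fry has no direction, so it could show no change of direction. Of the named genes 603 calls were lost and 12 gained over all fits with 1 array left out (3159 the same), and 238 were lost and 33 gained under other settings (4275 the same). Of the lists 69 calls were lost and 65 gained with 1 array left out, and 207 were lost and 108 gained under other settings. Days 8 to 13, the F test, the control interval and the number of list calls stayed within 1.5 times under every array left out (9069 to 9590, 8968 to 9877, 2495 to 3138 and 127 to 136). With 1 array left out, the lowest and highest counts were 115 and 805 for days 8 to 9, 749 and 2266 for days 9 to 10, 0 and 6 for days 10 to 11, 10 and 242 for days 11 to 12, and 122 and 770 for days 12 to 13. They were 1416 and 2179 for norflurazon at day 9, 16 and 114 at day 10, 359 and 649 for the interaction, and 259 and 340 for treated leaves between days 9 and 10. Fewer arrays lower the power, but removing some arrays raised the count, and the cause was not tested. Correlations ran from -0.567 to -0.494 for norflurazon with age and from 0.170 to 0.296 for control leaves with the time course.

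With only the compared groups in the fit, days 8 to 9 gave 16, days 9 to 10 704, days 11 to 12 3, days 12 to 13 2 and norflurazon at day 9 1202, with fewer arrays behind the variance. With all 30 arrays in 1 fit the counts were 1202, 3880, 12, 795 and 1352 for the 5 intervals in order of age, 1397 and 38 for norflurazon at days 9 and 10, 263 for the interaction and 383 for treated leaves between days 9 and 10. Only probe sets at or above percentile 50 (17393 in the time course, 16017 in the other experiment) gave 613, 3, 347 and 751 for days 8 to 9, 10 to 11, 11 to 12 and 12 to 13, 466 for norflurazon at day 10 and 896 for the interaction, with fewer genes to adjust over. Quantile normalization again gave 336 for days 11 to 12, and the cause was not tested. A change of at least 1 log2 kept 153, 289, 57 and 108 for days 8 to 9, 9 to 10, 11 to 12 and 12 to 13, 3544 for days 8 to 13, 191 and 43 for norflurazon at days 9 and 10, 172 for the interaction, 381 for control and 41 for treated leaves. An adjusted p under 0.01 kept 134, 633, 11 and 135 for the same 4 intervals, 960 and 16 for norflurazon, 187 for the interaction, 1889 for control and 202 for treated leaves.

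The replicate block gave 308, 2035, 0, 159 and 390 for the intervals and 130 list calls. Control day 10 minus norflurazon day 9, in place of the control interval, called 1510. With the labels of control and norflurazon day 9 exchanged, the interaction called 2190, treated leaves between days 9 and 10 3976, and norflurazon at day 9 the same 2248 with turned signs. The correlation of norflurazon with age was -0.868 over genes called between days 9 and 10, -0.673 over genes at or above the median level, and -0.208 with the norflurazon effect of day 9; that of control leaves with the time course was 0.521 over called genes. Of 290 list tests 1 was called with an estimated correlation, 95 with fry in 1 direction, 195 with its mixed p and 140 after quantile normalization again. Signal near background limits dim probe sets, and so the size of 18 of the 82 changes called among named genes between days 8 and 13, and saturation limits the brightest, such as RBCS1A.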

Other observations

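The lists of this part were chosen after the largest changes were seen, and so were the scores of development and of the clock.

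Genes that respond to low sulfur, phosphate and iron were among those that rose between days 9 and 10 of the time course. Of 9 sulfur genes 7 rose, among them the adenylylsulfate reductase genes APR3 by 2.57 ± 0.34, APR1 by 2.47 ± 0.35 and APR2 by 1.81 ± 0.27, beside LSU2 by 3.2 and SDI1, a repressor of glucosinolate synthesis, by 1.54 ± 0.45 (adjusted p = 0.0850 for the list with an estimated correlation). Of 13 phosphate genes 8 rose, among them the acid phosphatase gene PAP17 by 2.84 ± 0.44, SPX1 by 2.72 ± 0.45, SRG3 by 2.58 ± 0.50, the phosphatase gene PS2 by 2.57 ± 0.54, and the sulfolipid synthesis genes SQD2 by 1.58 ± 0.31 and SQD1 by 1.52 ± 0.29 (adjusted p = 0.0850 with an estimated correlation). Of 8 iron genes 5 rose, with the bHLH regulators BHLH100 by 2.68 ± 0.61, BHLH39 by 2.55 ± 0.66 and BHLH38 by 1.95 ± 0.57, and the transporter gene OPT3 by 1.34 ± 0.26 (adjusted p = 0.171 with an estimated correlation). The values of LSU2, SDI1, APR1, PS2 and BHLH38, whose day 9 means lie under the array median, are lower limits of their size. Not all of these calls held with 1 array left out: without day 9 replicate 3 the adjusted p of FRO3, BHLH100, BHLH39 and BHLH38 was 0.0501, 0.0762, 0.13 and 0.18, and without day 10 replicate 2 that of SDI1 and PS2 was 0.194 and 0.0622. The iron count of 5 became 3 and 1 without day 9 replicates 2 and 3, and 2 without day 10 replicate 2 or 3. The phosphate count of 8 became 5 without day 10 replicate 2 or 3, and the sulfur count ran from 5 to 8. Between days 11 and 12, 3 phosphate genes fell (adjusted p = 0.0850 with an estimated correlation). In the norflurazon experiment 5 sulfur, 7 phosphate and 3 iron genes rose between days 9 and 10 in control leaves, an interval that starts from the control arrays of day 9 that stood apart (adjusted p = 0.161, 0.0853 and 0.267 with an estimated correlation). In treated leaves 1, 2 and 1 rose, and 1 iron gene fell (0.574, 0.355 and 0.897). At day 10, 4 sulfur, 2 phosphate and 2 iron genes were lower with norflurazon (adjusted p = 0.0850, 0.0850 and 0.134 with an estimated correlation).

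Plastid-encoded genes, 67 probe sets, had 0 calls between days 9 and 10, where nuclear photosynthesis genes rose, and 16 higher and 3 lower calls between days 8 and 13 (adjusted p = 0.897 with an estimated correlation). A score of development, the mean of genes called higher minus that of genes called lower between days 8 and 13, was -1.42, -1.11, -0.47, -0.29, 0.09 and 0.54 on days 8 to 13 of the time course, on which it was defined. It was -0.89 ± 0.14 (SD, n = 3) and -0.75 ± 0.05 in control leaves at days 9 and 10, and -1.08 ± 0.07 and -1.08 ± 0.04 in treated leaves. The experiments look normalized apart, so these levels do not place the leaves on the ages of the time course. A clock score, evening minus morning genes, was -1.54 ± 0.06 in control and -1.40 ± 0.07 in treated leaves of day 9, a difference of 0.14 (SE 0.08). At day 10 it was -1.88 ± 0.17 and -1.26 ± 0.06, a difference of 0.62 (SE 0.08). In the time course the score went from -0.99 on day 8 to -2.17 on day 13, so the difference at day 10 does not tell an earlier or later harvest from a younger leaf.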
